A study of Mus musculus with 10 samples.

How the data were processed

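Bulk RNA was measured in lung tissue from wild-type mice given bleomycin, a DNA-damaging drug that injures the lung and leads to fibrosis. The mice had received bone marrow cells sorted by the activity of aldehyde dehydrogenase (ALDH), the enzyme family that oxidises aldehydes. The 10 samples comprised 5 recipients of cells with high ALDH activity (ALDHbr) and 5 recipients of cells with low ALDH activity (ALDHdim). No untreated sample and no sample given bleomycin without cells was analysed here, so each value is relative to the other transfer group. The labels number the samples of each group without saying that each came from a separate animal, so p-values measure the spread between these samples.

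Libraries were made by BRB-seq, per the labels' protocols, a 3' method in which each RNA sample receives a barcode during reverse transcription from an oligo-dT primer and the samples are then pooled and amplified together. The first read held a unique molecular identifier (UMI) of 10 nt and a sample barcode of 9 nt, and the second read gave 81 nt of the RNA. Because reads start near the 3' end, a count does not scale with transcript length. The submitters' processing notes list UMI-tools, Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2, together with the mouse build GRCm38 and the human build GRCh38, without giving their roles. The deposited barcode sheet holds 16 samples in 1 pool, the 10 lung samples and 6 samples of ALDHbr cells, 3 male and 3 female. The counts of those cells are not analysed here.

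The deposited table holds raw counts per gene, whole numbers that were not normalized, for 33347 mouse genes and 10 libraries. Whether counts were collapsed by UMI, whether counting used strand, and which gene annotation was used are not given in the sources used here. If UMIs were not collapsed, PCR copies add to the counts without adding molecules. Every gene identifier was found in GENCODE mouse release 21 on GRCm38, on the chromosome the table gives, and positions were taken from that annotation.

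Totals ranged from 588063 to 2002947 counts per library. Genes were kept by edgeR's filterByExpr with the group as design and a minimum count of 10, which left 10844 genes holding 97.3% of all counts. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, then glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are ALDHbr over ALDHdim on the log2 scale. Standard errors were taken from the fold change and its F statistic, and 95% intervals from the same fit. Levels are CPM computed over the tested genes' counts after TMM scaling, given as mean ± SD. The common biological coefficient of variation was 19.7%.

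The test was run on simulated data before use. In 5 simulations of the ALDHbr against ALDHdim comparison, counts for the 10844 genes were drawn from the libraries' own means, sizes and dispersions, with 200 genes changed. The test recovered 17.2% of genes changed by 1.5-fold, 69.6% of those changed by 2-fold, 94% of those changed by 3-fold and 97.2% of those changed by 4-fold. Of all its calls 5.53% were false. Genes were drawn independently in these simulations, unlike genes in tissue, and a list of 20 genes raised by 1.5-fold had an unadjusted camera p under 0.05 in 5 of 5 simulations, against 1 of 5 for an unmoved list.

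Before the data were examined, 45 gene lists of 594 entries were written for fibrotic lung, its resident and recruited cells, general programs and tissues that a piece of lung can carry with it. Lists with at least 5 tested genes were tested by camera in limma 3.58.1 with the preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, whose directional p asks whether a list's genes move on balance one way, were run beside it. A list score is the mean over its tested genes of log2 CPM, with a prior count of 2, centred per gene. Library composition was compared by an exact two-sided permutation test over all 252 assignments of the 10 libraries, whose smallest p is 0.0079.

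Genes are named by a rule fixed before the data were examined. The rule takes all genes past the threshold, up to 10 in each direction, filled up to 5 in each direction by smallest p when fewer pass, leaving out predicted and clone names. It adds up to 4 members of smallest p, in the list's direction, of each list past its threshold, and a fixed set of lung and fibrosis genes. Alternatives were another scaling (DESeq2 size factors or upper quartile), no filter or a mean count of at least 10, DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a term in the model, removal of hemoglobin, immunoglobulin and mitochondrial genes, other thresholds, and leaving out each library in turn. Plots were drawn with matplotlib 3.10.9.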

Results

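Gene expression was measured in 10 lung samples of wild-type mice given bleomycin, 5 from recipients of marrow cells in which ALDH activity was high (ALDHbr) and 5 from recipients of marrow cells in which it was low (ALDHdim). The comparison asks how lung expression differed between recipients of the 2 kinds of marrow cell. The ALDHbr libraries 1 to 5 held 1522283, 588063, 854577, 1260417 and 1258362 counts, and the ALDHdim libraries 1 to 5 held 1401757, 2002947, 1227624, 1181037 and 1817519. Transcripts of lung epithelium were among the most abundant in both groups. Scgb1a1, the secretoglobin of airway club cells, averaged 23490 ± 9894 CPM over the 10 libraries, and Sftpc, surfactant protein C of alveolar type 2 cells, averaged 21873 ± 6653 CPM. No pair of libraries held the same counts (lowest chi-square per degree of freedom 2.4), and each was counted as a separate sample.

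Col1a1, Fn1, Col3a1 and Timp1, genes of the fibrotic matrix, had lower mean levels in ALDHbr recipients, by less than the SD within either group. Col1a1, a chain of type I collagen, averaged 374 ± 230 CPM in ALDHbr recipients and 563 ± 296 CPM in ALDHdim recipients (SD, n = 5 each), a log2 fold change of −0.57 (SE 0.58). Fn1 (fibronectin) differed by −0.50 (SE 0.64), Col3a1 by −0.30 (SE 0.50) and Timp1, an inhibitor of matrix metalloproteases, by −0.34 (SE 0.70), or by 0.17 with limma-voom. Of the 20 genes in the list of fibrillar collagen and fibrotic matrix, 19 had lower and 1 had higher estimates, with a median of −0.20, and 0 passed when adjusted over the list alone or over all genes tested. The camera test of the list gave an adjusted p of 0.050446, just over the threshold, and the adjusted p was 0.94 with an estimated correlation. That estimate was 0.70, against the preset 0.01. The list was past the threshold with the preset correlation when ALDHdim 2 was left out (median −0.40, adjusted p = 7.7e-06), and likewise without ALDHbr 5 (−0.44, 0.000101), ALDHbr 1 (−0.29, 0.012), ALDHbr 4 (−0.31, 0.017) or ALDHdim 3 (−0.28, 0.019). The median was nearer to 0 without ALDHbr 2 (−0.05, adjusted p = 0.83), ALDHdim 5 (−0.05, 0.41), ALDHbr 3 (−0.08, 0.42) or ALDHdim 4 (−0.12, 0.28). With the preset correlation the list was also past the threshold under DESeq2 size factors (adjusted p = 0.043), with a mean count of at least 10 (0.049) and without both ALDHbr 3 and ALDHbr 5 (0.019). Across libraries the mean level of these matrix genes spanned 4.25-fold within the ALDHbr group and 3.23-fold within the ALDHdim group.

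**Figure D1:**
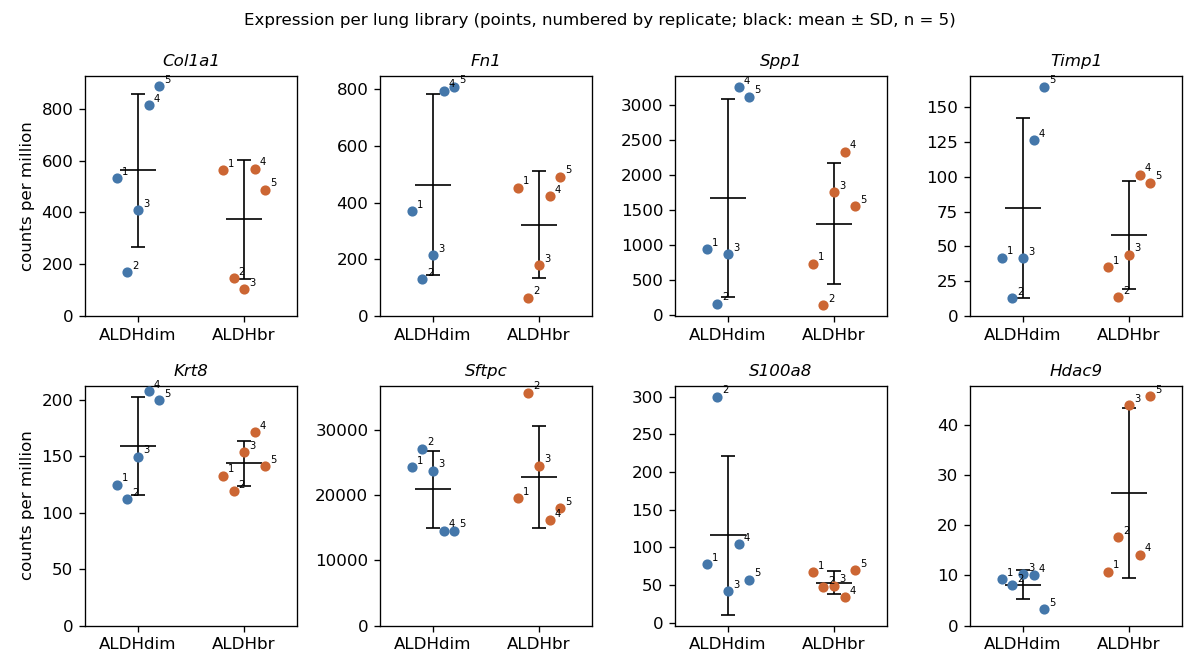
Levels in CPM of 8 named genes (vertical axes, linear) in each lung library of the ALDHdim and ALDHbr groups, with points numbered by replicate and black marks for the mean ± SD of 5 libraries. Col1a1, Fn1, Spp1, Timp1, Krt8 and Sftpc overlap between the groups, S100a8 is highest in ALDHdim 2 at 300.2 CPM, and Hdac9 is highest in ALDHbr 3 and ALDHbr 5.

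Other markers of fibrotic injury and its cells overlapped in the same way. Spp1 (osteopontin), a marker of profibrotic macrophages, averaged 1301 ± 864 CPM in ALDHbr and 1667 ± 1416 CPM in ALDHdim recipients, a log2 fold change of −0.35 (SE 0.85). Arg1 (arginase 1), found in alternatively activated macrophages, differed by −0.77 (SE 0.73) at mean levels of 10.7 and 19.7 CPM. Acta2, the smooth muscle actin of myofibroblasts, differed by −0.08 (SE 0.19), and Tgfb1 by 0.15 (SE 0.20). In the epithelium, Sftpc differed by 0.13 (SE 0.25), Ager, a receptor of alveolar type 1 cells, by 0.09 (SE 0.17), Krt8, a keratin of transitional alveolar cells, by −0.13 (SE 0.17), and Scgb1a1 by 0.01 (SE 0.32). Pecam1 of endothelium differed by −0.04 (SE 0.22) and Mki67 of dividing cells by 0.16 (SE 0.50). Cd3e of T cells averaged 8.09 ± 4.18 CPM in ALDHbr and 8.08 ± 3.21 CPM in ALDHdim recipients, and Foxp3 of regulatory T cells 2.17 ± 2.23 and 0.78 ± 1.46 CPM. Both were below the count filter, and neither was tested.

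No gene passed the threshold. Of 10844 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower in ALDHbr recipients, with a smallest adjusted p of 0.99925. At an unadjusted p under 0.05 there were 402 genes, 231 higher and 171 lower, against 542 expected by chance. Without ALDHbr 1 there were 1141 of 11024 genes at that level, against 551 expected by chance, and 0 passed the threshold (smallest adjusted p 0.30). DESeq2 also called 0 of 33347 genes (1465 at an unadjusted p under 0.05, against 1667 expected by chance), as did limma-voom (690 of 10844, against 542 expected). The median 95% interval reached 0.43 to either side on the log2 scale (1.35-fold), and the whole interval lay within 2-fold in either direction for 9794 genes (90.3%). Several fibrosis genes had wider intervals. As a fold, the interval ran from 0.27 to 1.66 for Col1a1, 0.26 to 1.91 for Fn1 and 0.37 to 1.77 for Col3a1. It ran from 0.26 to 2.35 for Timp1, 0.21 to 2.94 for Spp1 and 0.19 to 1.79 for Arg1. Acta2 (0.72 to 1.24) and Tgfb1 (0.83 to 1.48) lay within 2-fold.

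The genes with the smallest p are described here as not past the threshold, each with an adjusted p of 0.99925. The higher ones in ALDHbr recipients included Cebpd, a transcription factor of the acute-phase response, at 225 ± 42.6 against 148 ± 39.7 CPM (log2 fold change 0.60, SE 0.18). Snhg18, a non-coding host gene of small nucleolar RNA, differed by 0.61 (SE 0.16). Ntpcr, a nucleoside triphosphatase, differed by 0.70 (SE 0.19) and Ndfip2, an adaptor of Nedd4-family ubiquitin ligases, by 0.48 (SE 0.14). Hdac9, a class IIa histone deacetylase, differed by 1.71 (SE 0.45) at 26.5 ± 17.0 against 8.18 ± 2.86 CPM. Its level was 44.0 CPM in ALDHbr 3 and 45.8 CPM in ALDHbr 5, libraries that stand apart in the number of genes detected, and its log2 fold change was 0.76 without both. The smallest p of all belonged to Bbof1, a basal body protein of ciliated cells, at 7.72 ± 2.12 against 17.1 ± 2.50 CPM (−1.18, SE 0.26). Pigr, the receptor that carries polymeric immunoglobulin across epithelium, was at 36.6 ± 8.28 against 57.8 ± 11.2 CPM (−0.67, SE 0.19). Elovl6, a fatty acid elongase, differed by −0.98 (SE 0.27), Anxa8 (an annexin) by −0.51 (SE 0.15) and Fastk, a kinase-like protein of mitochondria, by −0.53 (SE 0.16). With no low-count filter, Hdac9 (adjusted p = 6.2e-05), Bbof1 (0.029) and Pigr (0.030) were among 185 genes past the threshold, while their adjusted p was 0.30 or more under each other alternative. On GRCm38, Cebpd lies on chromosome 16 from 15887286 to 15891031, Hdac9 on chromosome 12 from 34047580 to 34917095, Bbof1 on chromosome 12 from 84409071 to 84442887, Pigr on chromosome 1 from 130826684 to 130852249, and Col1a1 on chromosome 11 from 94936224 to 94953042. These are whole-gene positions, and counts were summed per gene.

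Of 38 gene lists tested, 3 passed with the preset correlation. The mature neutrophil list was lower in ALDHbr recipients (9 genes, 7 lower and 2 higher, median −0.72, adjusted p = 0.015; adjusted p = 0.94 with an estimated correlation). S100a8, a subunit of calprotectin, was at 53.4 ± 15.1 CPM in ALDHbr and 116 ± 105 CPM in ALDHdim recipients (−1.13, SE 0.55). Its partner S100a9 differed by −1.26 (SE 0.64), Retnlg by −0.89 (SE 0.46) and the cytokine gene Il1b by −0.71 (SE 0.40). Without ALDHdim 2, where S100a8 reached 300.2 CPM, the list's median was −0.30 with an adjusted p of 0.12, and S100a8, S100a9, Retnlg and Il1b differed by −0.37, −0.35, −0.47 and −0.30. Without ALDHbr 1 the median was −1.08 with an adjusted p of 0.018. The cardiac muscle list was lower as well (8 genes, 7 lower and 1 higher, median −0.40, adjusted p = 0.012; adjusted p = 0.94 with an estimated correlation). In mice, cardiac-type muscle surrounds the pulmonary veins. Its members Tnnt2, Sln, Tnni3 and Myl4 differed by −0.62 (SE 0.23), −0.72 (SE 0.29), −0.61 (SE 0.26) and −0.43 (SE 0.27). Without ALDHbr 4 the list's median was −0.32 with an adjusted p of 0.086. It was −0.63 without ALDHbr 1 and −0.25 without ALDHbr 5, both past the threshold, and without both ALDHbr 3 and ALDHbr 5 it was −0.18 with an adjusted p of 0.11. The mesothelium list, of the cells that line the pleura, was higher (5 genes, 4 higher and 1 lower, median 0.32, adjusted p = 0.022; adjusted p = 0.94 with an estimated correlation). Lrrn4 differed by 0.78 (SE 0.28), Upk1b by 0.39 (SE 0.23), Upk3b by 0.32 (SE 0.36) and Msln (mesothelin) by 0.22 (SE 0.18). That call was lost without ALDHbr 1 (median 0.28, adjusted p = 0.051), ALDHbr 2 (0.24, 0.080), ALDHdim 4 (0.24, 0.21) or ALDHdim 5 (0.29, 0.073). None of the 3 calls held with fry either (adjusted p = 0.97 for each), and 0 genes passed in any list when adjusted over the list alone.

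**Figure D2:**
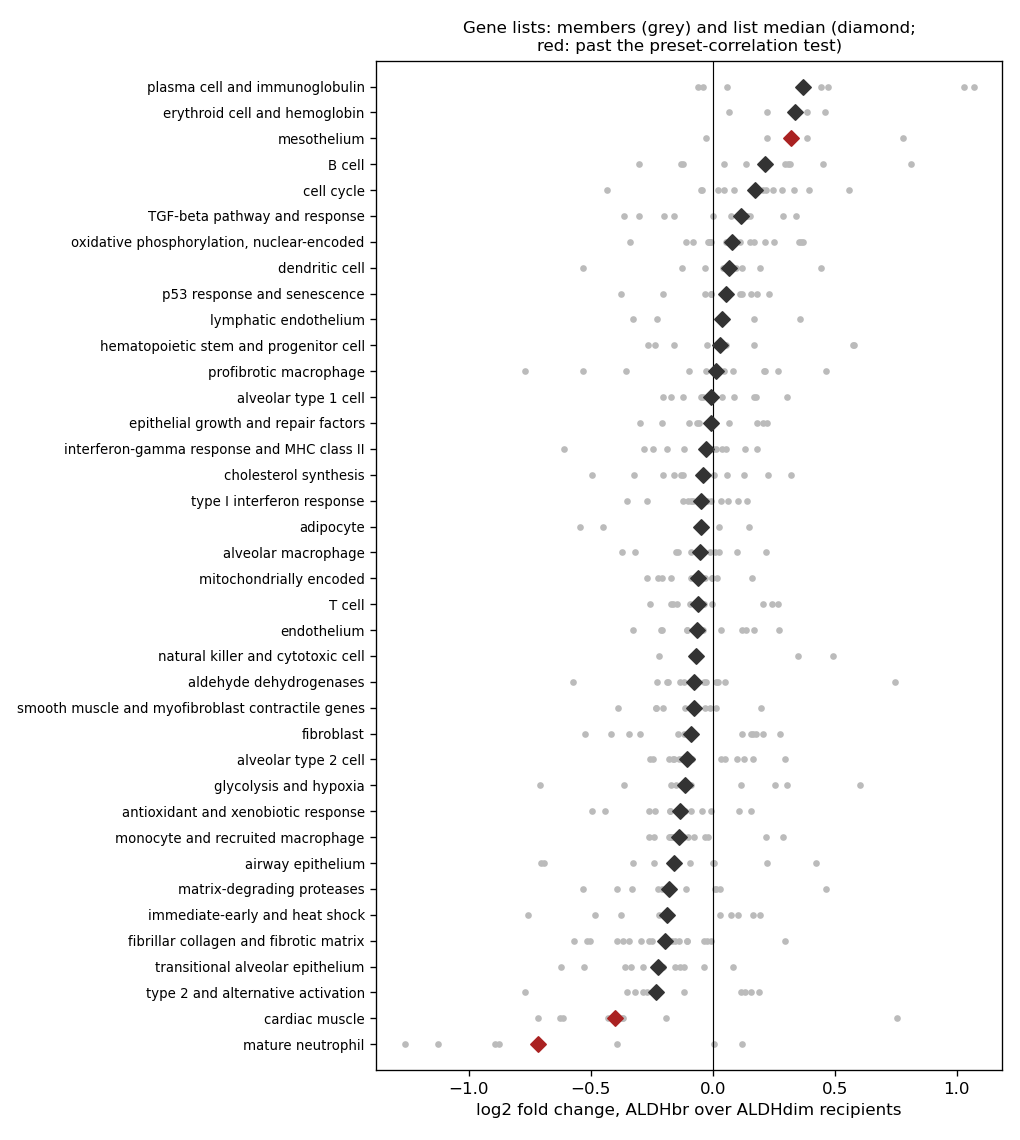
Log2 fold change, ALDHbr over ALDHdim recipients (horizontal axis), for the tested members of 38 gene lists (grey points) and each list's median (diamonds). The 3 lists past the threshold with the preset correlation are red, with medians of −0.72 (mature neutrophil), −0.40 (cardiac muscle) and 0.32 (mesothelium).

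Lists of other lung cells and programs did not pass in the main test. In the epithelium, the transitional alveolar list had 11 of 12 genes with lower estimates (median −0.22, adjusted p = 0.10), the airway list a median of −0.16 (adjusted p = 0.10), the alveolar type 2 list −0.11 (adjusted p = 0.57) and the alveolar type 1 list −0.0078 (adjusted p = 0.98). With the preset correlation the transitional list passed, as lower, without ALDHbr 4, ALDHbr 5, ALDHdim 1 or ALDHdim 2. The airway list did so without ALDHbr 2 or ALDHbr 3. With an estimated correlation over all libraries both had an adjusted p of 0.94. Smooth muscle and myofibroblast contractile genes had a median of −0.08 (adjusted p = 0.14), fibroblast genes −0.09 (adjusted p = 0.36) and endothelial genes −0.07 (adjusted p = 0.91). Among macrophage lists the medians were −0.14 for monocytes and recruited macrophages, −0.05 for alveolar macrophages and 0.01 for profibrotic macrophages, with adjusted p of 0.55, 0.49 and 0.90. The plasma cell and immunoglobulin list had a median of 0.37 (adjusted p = 0.31), the B cell list 0.22 (adjusted p = 0.42) and the T cell list −0.06 (adjusted p = 0.79). TGF-beta pathway genes had a median of 0.11 (adjusted p = 0.98), the type I interferon response −0.05 (adjusted p = 0.33) and the cell cycle 0.17 (adjusted p = 0.59). Some of these lists passed, as lower, with the preset correlation when a library was left out. Contractile and fibroblast genes did so without ALDHbr 1, and recruited macrophages and the type I interferon response without ALDHdim 2. The antioxidant and xenobiotic list (median −0.14, adjusted p = 0.12) did so without ALDHbr 2, ALDHdim 1 or ALDHdim 3. With an estimated correlation over all libraries their adjusted p was 0.94 or more. The 12 tested aldehyde dehydrogenase genes had a median of −0.08 (adjusted p = 0.55), and 10 genes of hematopoietic stem and progenitor cells a median of 0.03 (adjusted p = 0.55). For 4 lists (natural killer and cytotoxic cells, profibrotic macrophages, alveolar type 1 cells and lymphatic endothelium) the median, mean and camera direction differed in sign. A further 7 lists had too few tested genes: granulocyte precursors, eosinophils with basophils and mast cells, regulatory T cells, inflammatory cytokines and chemokines, platelets with megakaryocytes, skeletal muscle and thymus.

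Library composition did not separate the groups either. Hemoglobin genes took 0.99 ± 0.39% of counts in ALDHbr and 0.82 ± 0.59% in ALDHdim recipients (n = 5 each, exact permutation p = 0.60). Immunoglobulin genes took 0.19 ± 0.15% and 0.11 ± 0.043% (exact permutation p = 0.38), and mitochondrial genes 6.86 ± 1.34% and 7.20 ± 1.11% (exact permutation p = 0.64). Total counts averaged 1096700 ± 371280 in the ALDHbr and 1526200 ± 366030 in the ALDHdim libraries (exact permutation p = 0.13). Adjusted over 6 measures, p ranged from 0.76 to 0.98. The ALDHbr libraries 3 and 5 detected 24722 and 25377 genes. At an equal depth of 588063 counts they detected 22807 and 21577, against at most 18056 in any other library. The leading principal component held 30.1% of the variance and did not separate the groups (exact permutation p = 0.91). In both groups it was lowest at replicate number 2 (−43.5 in ALDHbr, −26.9 in ALDHdim) and highest at number 5 (22.8 and 18.7). At number 3 the groups differed in sign (16.2 and −2.59). Whether shared numbers mark a batch is not given in the sources used here.

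**Figure D3:**
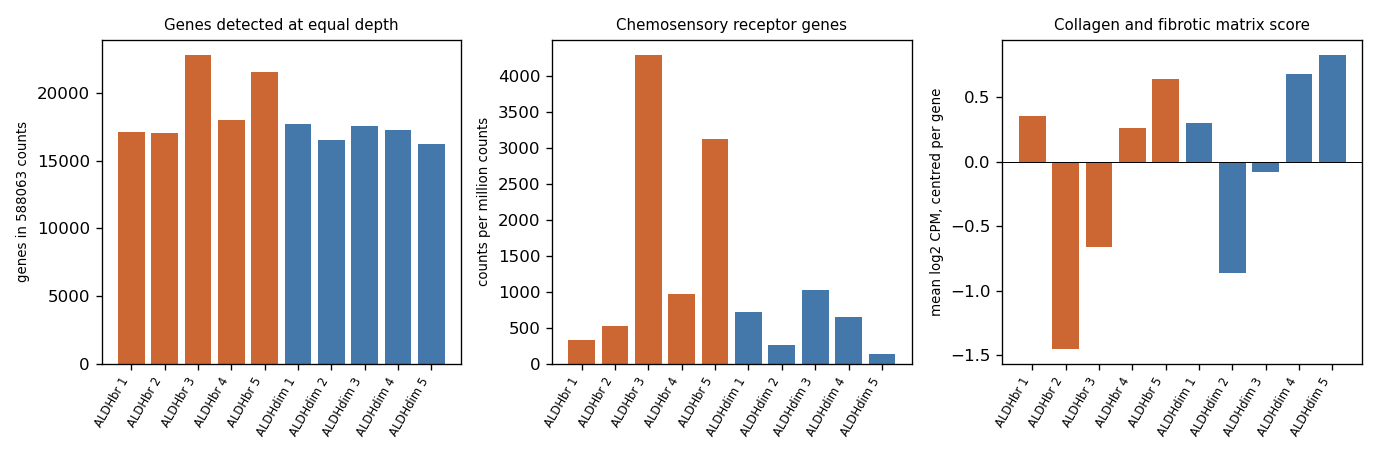
For each of the 10 libraries (ALDHbr orange, ALDHdim blue), bars give the genes detected at an equal depth of 588063 counts, the CPM (of total counts) summed over chemosensory receptor genes, and the mean log2 CPM of the collagen and fibrotic matrix list centred per gene. ALDHbr 3 and ALDHbr 5 are highest in the first 2 panels, and the matrix score runs from −1.45 in ALDHbr 2 to 0.83 in ALDHdim 5.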

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

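Of 164 sets of 5 values (named genes, list scores and composition measures within a group), 11 had a library whose gap to its nearest neighbour took an unusually large share of the group's range, against 8.2 expected by chance, since chance flags about 1 set in 20. Both explanations of the neutrophil difference below were tested only after the result was seen.

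ALDHdim 2 stood apart from the other ALDHdim libraries in several ways. Its neutrophil genes were high, with S100a8 at 300.2 CPM against 41.7 to 104 CPM in the other ALDHdim libraries (share of range 0.757), S100a9 at 484.3 against 57.0 to 113 CPM (0.869) and Il1b at 60.03 against 20.4 to 25.8 CPM (0.864). Its cell cycle score was low at −1.19 against 0.12 to 0.43 (0.811), though ALDHbr 2 was also low at −1.05. The neutrophil list's lower level in ALDHbr recipients may come from ALDHdim 2. Without that library the list's median log2 fold change was −0.30008, with an adjusted p of 0.12, against −0.72 with it. More blood in that lung piece is argued against by its hemoglobin share of 1.2577%, within the 0.16 to 1.37% of the other 9 libraries. A difference between the transfer groups stays open, as does what sets this library apart.

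ALDHbr 2, the library of lowest depth, had Scgb1a1 at 44490 CPM against 15250 to 23270 CPM in the other ALDHbr libraries (0.726), and a p53 response and senescence score of −0.68 against 0.06 to 0.26 (0.791). That score was also low in ALDHdim 2, at −0.72. ALDHbr 1 had a fibroblast score of 0.45 against −0.28 to −0.10 (0.748) and a score of mitochondrially encoded genes of −0.52 against −0.04 to 0.15 (0.72). ALDHdim 4 had Anxa8 at 50.5 CPM against 39.1 to 41.9 CPM (0.758) and Foxp3 at 3.37 CPM against 0 to 0.55 CPM (0.837), the latter from very few counts. ALDHdim 1 had a cardiac muscle score of −0.42 against 0.21 to 0.44 (0.727).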

How the results depend on the processing

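The count of 0 genes held under each alternative but the omission of the low-count filter, which gave 185 genes at the same threshold, 182 higher and 3 lower. The median log2 fold change was 0.23 there and 0.28 with DESeq2, both over 33347 genes, against 0.01 over the 10844 genes of the main test. Only 8 of the 185 genes had enough counts for the main test, their median count over all 10 libraries was 43, and a median of 70.6% of the counts of the higher ones lay in ALDHbr 3 and 5, which hold 16.1% of all counts. Leaving out ALDHbr 3 and 5, an alternative chosen after seeing the data, gave 0 genes and 4 lists.

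The number of lists past the threshold, 3 in the main test, was 0 with an estimated correlation, 0 with fry, 4 with DESeq2 size factors, 4 with a mean count of at least 10, and 2 to 10 when each library was left out in turn (10 without ALDHdim 2). The median estimated correlation between the genes of a list was 0.35, against the preset 0.01. The estimate was 0.32 for cardiac muscle, 0.27 for mature neutrophil, 0.19 for mesothelium and 0.70 for the fibrotic matrix list. A p with the preset correlation can therefore be too small for these lists. Why the number changed when libraries were left out was not tested. Samples of the 2 groups share replicate numbers. Deviations of same-numbered samples correlated at 0.06 to 0.37, over 0.1 for 4 of 5 numbers, and 3 of 5 correlated best with their own number, so the criterion for pairing, over 0.1 for every number, was not met. Whether the numbers mark a shared batch is not given in the sources used here. With the replicate number as a block, 0 genes passed (727 at an unadjusted p under 0.05) and 8 lists, all with the preset correlation. Among them were the fibrotic matrix list (adjusted p = 1.6e-08) and the transitional alveolar and airway lists, each as lower. With the replicate block and an estimated correlation 0 lists passed (adjusted p = 0.79 for the matrix list), and with the replicate block and fry 0 passed (0.67). Both settings were chosen after seeing the data. Over all settings that adjusted p ranged from 1.6e-08 to 0.97. The matrix score was lower in ALDHbr at 4 of 5 numbers and lowest at number 2 in both groups.

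Reversals concerned values that did not pass their tests. Leaving out ALDHbr 3 and 5 gave Acta2 0.15, Pecam1 0.16 and Mki67 −0.33. Limma-voom gave Timp1 0.17, Ager −0.021 and Scgb1a1 −0.12, and Scgb1a1 was −0.10 with no filter, −0.0028 with DESeq2 and −0.036 with the replicate block. Without each library in turn, the log2 fold changes ranged from −0.27 to 0.038 for Acta2, −0.64 to 0.18 for Timp1, −0.67 to 0.030 for Spp1, −0.10 to 0.24 for Sftpc, −0.0099 to 0.17 for Ager, −0.36 to 0.19 for Scgb1a1, −0.22 to 0.10 for Pecam1 and −0.30 to 0.42 for Mki67. The difference in mitochondrial percent ranged from −0.64 to 0.11 and in the percent of the 10 most abundant genes from −0.90 to 0.64. The cause was not tested. Of the other values 755 kept their direction and side of the threshold, 12 moved past it and 19 fell short of it. The count filter kept Cd3e and Foxp3 out of the test.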

Other observations

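Fibrotic matrix genes differed together among samples of both groups. Over 10 libraries, the score of the fibrotic matrix list rose with that of TGF-beta pathway genes (Pearson r = 0.968, permutation p = 4e-05, adjusted p = 6e-04; Spearman rho = 0.915, p = 0.00058). Members of the TGF-beta list did not all move this way. From ALDHbr 2 and ALDHdim 2 to ALDHdim 4 and 5, Thbs1 went from 37 and 63 to 287 and 196 CPM. Smad7 went from 170 and 167 to 85 and 87 CPM, and Bambi from 39 and 36 to 23 and 21 CPM. The matrix score also rose with transitional alveolar epithelium (r = 0.854, adjusted p = 0.0092; rho = 0.782, adjusted p = 0.039), which includes Krt8, with p53 response genes (r = 0.859, adjusted p = 0.012; rho = 0.794, adjusted p = 0.039) and with monocytes and recruited macrophages (r = 0.823, adjusted p = 0.014; rho = 0.782, adjusted p = 0.039). Airway epithelium fell as the matrix score rose (r = −0.787, adjusted p = 0.018; rho = −0.745, adjusted p = 0.042). The alveolar type 2 list passed by rank alone (r = −0.675, adjusted p = 0.061; rho = −0.733, adjusted p = 0.042), and hemoglobin percent by neither measure (r = −0.65, adjusted p = 0.061; rho = −0.685, adjusted p = 0.066). Hemoglobin took 0.16% and 0.20% of counts in ALDHdim 4 and 5, the libraries of highest matrix score, and its list spanned from −1.96 in ALDHdim 4 to 0.93 in ALDHbr 4 on the log2 scale. Without ALDHbr 2 and ALDHdim 2, the libraries farthest from the median, r was 0.895 for TGF-beta genes, 0.629 for transitional epithelium, 0.586 for recruited macrophages, 0.54 for p53 response genes −0.538 for airway epithelium, −0.491 for alveolar type 2 cells and −0.795 for hemoglobin percent. The profibrotic macrophage relation (r = 0.809, adjusted p = 0.018; rho = 0.745, adjusted p = 0.042) fell to 0.385 and the cell cycle relation (r = 0.774, adjusted p = 0.023; rho = 0.539, adjusted p = 0.17) to 0.259, so both rest largely on those libraries. Relations with transitional epithelium, recruited macrophages, p53 response, airway epithelium and alveolar type 2 cells weakened too. No r without those libraries was tested, so whether these relations hold without them stays open. Permutation tests used 100000 resamples and adjustment covered 15 relations, and no list shares a gene with the matrix list, though the transitional list shares Cdkn1a with the p53 list and Lgals3 with the profibrotic macrophage list. Over all 10 libraries, no relation passed for fibroblast genes (r = 0.223, adjusted p = 0.61; rho = 0.139, adjusted p = 0.81; r = 0.2 without those 2 libraries) or contractile genes (r = 0.067, adjusted p = 0.91; rho = −0.0909, adjusted p = 0.87; r = 0.42). That pooled value does not describe each group, since in ALDHdim the contractile score went from 0.25 in the library of lowest matrix score to −0.05 in that of the highest. Correlations are given here over at least 6 samples, so none is given within a group of 5.

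Of the tests below, those of the injury gradient, of thinned libraries, of unspecific priming, of gene numbers at equal depth and of the transfer of ALDHbr cells were chosen after the result was seen. The matrix score spanned 2.28 on the log2 scale (4.85-fold), and the group difference explained 5.8% of its variance. That share was taken without the replicate number as a term in the model. Unequal counting depth is argued against, as the span was 2.09 on average over 20 thinnings of each library to 588063 counts. Unspecific priming confined to ALDHbr 3 and 5 is argued against as well, as the 8 libraries without them alone spanned 2.28. Priming within those 8 libraries was not compared with the score and stays open. A hypothesis is that the lungs, or the pieces sampled, differed in how far the injury had gone. Its test was the lowest r of profibrotic macrophage, transitional epithelium and cell cycle scores with the matrix score after removal of group means, which was 0.8. Its limit is that all 3 relations lean on ALDHbr 2 and ALDHdim 2. Without these libraries, and with group means kept, r was 0.385, 0.629 and 0.259. The permutations took the libraries as independent. Yet in both groups the matrix score was lowest at replicate number 2 (−1.45 in ALDHbr, −0.86 in ALDHdim) and highest at number 5 (0.64 and 0.83). Numbers 1, 3 and 4 had scores of 0.35, −0.66 and 0.26 in ALDHbr and 0.30, −0.08 and 0.68 in ALDHdim. The order of the numbers by score was thus the same in both groups but for numbers 1 and 4. The replicate number was used as a block for the comparison of groups, not for these relations. Something shared by samples of the same number stays open. A property of the libraries that goes with their total count stays open. The r with log total counts was 0.549 (permutation p = 0.099, adjusted p = 0.15; rho = 0.309, adjusted p = 0.48), 0.512 after removal of group means and 0.771 without ALDHbr 2 and ALDHdim 2, yet those were the shallowest and the deepest library and had the lowest and the second lowest matrix score, and RNA quality values were not analysed here. The pooled value does not describe each group. In ALDHbr, scores were lowest in the libraries of lowest total, ALDHbr 2 (−1.45) and ALDHbr 3 (−0.66). In ALDHdim, the library of highest total, ALDHdim 2, had the lowest score (−0.86), and that of lowest total, ALDHdim 4, had 0.68.

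The larger gene numbers of ALDHbr 3 and 5 are hard to ascribe to depth, since the lower of the pair was 19.5% above any other library at equal depth. Reads from genomic DNA or other unspecific priming are a candidate explanation. Olfactory, vomeronasal and trace amine receptor genes, which lung is not known to express widely, summed to 4284 and 3115 CPM of total counts in the pair, and the lower value was 3.05 times the highest of the other 8 libraries. A rise in every ALDHbr recipient is argued against, as ALDHbr 1 and ALDHbr 2 detected fewer genes at equal depth (17148 and 17044) than the highest ALDHdim library (17705). ALDHbr 4 was above that library at 18056, so a shift in part of the group stays open. An effect in ALDHbr 3 and 5 alone was not tested.

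Of the 126 splits of the libraries into 5 and 5, 100 were fitted, the real one included. For genes past the threshold this tests nothing, as all 100 splits reach the real count of 0. Genes passed in 8 of them, with 653 in the highest. Chance could not be excluded for the other counts. At an unadjusted p under 0.05, 45 of the 100 splits, the real one included, had at least the real 402, and the highest other had 2102. For lists, 90 of the 100 had at least the real 3, with a median of 9 and a highest of 25 in the others. The split with 653 genes set ALDHbr 1 and 2 with ALDHdim 1, 2 and 3 against the rest, so both samples numbered 1 and 2 lay opposite both numbered 4 and 5. A count this far above the real one points to some structure of the samples, but the split was picked as the highest and what it follows was not tested.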
